A study of Mus musculus with 9 samples.

How the data were processed

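RNA was measured in 9 libraries, 3 per group, from mouse bone marrow cells sorted by flow cytometry as MEP. Per the labels, the RNA was extracted with a PicoPure kit and the libraries were made with Smart-Seq2, which copies whole transcripts by way of their poly(A) tails without molecular identifiers or strand. Groups follow the genotype in the labels, VF with SclCre and V617F, E12 with SclCre and the exon 12 allele, and WT. The number of weeks after tamoxifen is also from the labels, 12 for VF and WT and 6 for E12.

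The deposited gene counts are whole numbers for 17769 genes with Entrez identifiers, symbols and a gene length given by the authors. Per the submitters' processing notes STAR and limma were used with the builds GRCm38 and mm10, and the notes give no versions or roles. The counting tool and the annotation are not given in the sources used here. The authors also deposited expression levels on a log2 scale. Their sorted values differed between libraries by at most 0.017 in the upper part of the range and their order was that of the counts (Spearman correlation 1), which is what quantile normalization gives, though no source used here states the step. Those levels served only as an alternative. The mitochondrially encoded genes had 0 members in the counts, and their list was not tested. Total counts per library ran from 19256431 to 39736096.

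Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which kept 13608, libraries were scaled with TMM factors, and all 9 libraries entered 1 quasi-likelihood fit (glmQLFit and glmQLFTest) with the group as its only term. Each p is two-sided and adjusted by Benjamini-Hochberg over all tested genes, and genes under 0.05 were called. Adjusted p-values of single genes are from this test unless another tool is named. With 3 libraries against 3, an exact permutation test of 1 gene cannot go below 0.1. CPM were computed with the TMM factors. Where a group had no count, a fold is a lower bound against 3 counts over the group, and with 1 to 3 counts it is a ratio with its exact 95% binomial counting interval.

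The comparisons, tests, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Of 33 lists, made from textbook knowledge and not from these samples, 32 had members to test. They cover metabolism (glycolysis, transport of glucose, lactate and pyruvate, pentose phosphate pathway, pyruvate dehydrogenase and the tricarboxylic acid cycle, complex I, complexes III to V, fatty acid oxidation and synthesis, cholesterol, serine and one-carbon, nucleotide and heme synthesis, iron, glutathione), responses (amino acid response, endoplasmic reticulum chaperones, hypoxia, JAK-STAT5, interferon, p53, immediate early genes), the S phase, the G2 and M phase, ribosomal proteins, and markers of erythroid, megakaryocyte, stem, neutrophil, monocyte, B, T and NK, and mast cells with basophils and eosinophils. Each was tested against all other genes with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 96 tests. Of these 43 passed, 0 with an estimated correlation and 55 by fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. Counts of called members are also given adjusted over the list alone.

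Genes are named by a rule. Per comparison it takes the 6 called genes with the largest log2 fold change in each direction among those with at least 10 CPM in the higher group and no overlap between the groups, and up to 3 members of each list with the smallest p. It adds 4 genes in each direction that changed most in both comparisons with WT, the genes Jak2, Cish, Socs2, Pim1, Pfkfb3, Slc2a1, Hk2, Ldha and Epor, and genes on the sex chromosomes. Some genes that met the rule are not reported here. Genes outside the rule are said to be named after their values were seen. Positions are 1-based on GRCm38 and come from a RefSeq table that matched 99.7% of the genes.

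Alternatives were RLE and upper-quartile factors, other filters, DESeq2 1.42.0, limma-voom, limma on the deposited levels, fits of only the 2 groups compared, a fold threshold, library sizes without hemoglobin genes, a replicate block, and leaving out each library. Chosen after seeing the data were offsets for gene length and GC content (known for 90.2% of genes), leaving out WT 50 and E12 5 together, only genes with a count in every library, library sizes without Rn45s, and the list results with 2 groups alone, with the offsets or without WT 50 and E12 5. Pseudocounts were not varied, since the deposited levels are already log2. The edgeR fit was tested on simulated counts with 200 of 13608 genes changed. It found 72%, 75% and 75% of 8-fold changes for VF against WT, E12 against WT and E12 against VF, 2%, 0% and 1% of 2-fold changes, and made 1, 7 and 5 false calls. Figures were drawn with matplotlib 3.10.9.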

Results

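The libraries come from mouse bone marrow cells sorted by flow cytometry as MEP, the usual name for megakaryocyte-erythroid progenitors, which give rise to platelet-forming megakaryocytes and to red cells. Jak2 is the kinase that passes on signals from the erythropoietin receptor and other cytokine receptors, and mutations that activate it drive myeloproliferative neoplasms. Per the labels, the mutations were induced with 5 daily tamoxifen injections in mice carrying SclCre, a recombinase. The group named VF carried the V617F mutation, the group named E12 carried a mutation in exon 12, and WT is the control. Each group has 3 libraries. The VF and WT cells were taken 12 weeks after tamoxifen and the E12 cells after 6 weeks, so E12 differs from both other groups in genotype and in time. The series concerns metabolism in cells with mutant Jak2, so the comparisons below cover metabolic genes together with genes of the blood lineages. The labels do not say whether replicates are separate mice, and p-values then measure only the spread between these samples, which may be technical. Levels are normalised read counts relative to library size (CPM), as mean ± SD with n = 3 per group.

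Total counts ran from 19256431 to 21331168 in VF, from 20328414 to 23499914 in E12 and from 33838681 to 39736096 in WT. Although sequenced most deeply, the WT libraries had the most genes without a count, 27.2% to 30.1% against 10.7% to 12.4% in VF and 12.4% to 18.7% in E12. They also held more short transcripts. Genes under 1 kb took 27.9%, 14.1% and 11.2% of the counts in WT 50, WT 51 and WT 52, against 8.2% to 9.0% in VF and 6.9% to 8.8% in E12, and genes over 5 kb took 4.4% to 7.9% in WT against 14.2% to 16.3% in the mutant libraries. The WT libraries also carry facility numbers from another series than the mutant ones, so genotype and library series cannot be told apart. Log2 CPM correlated across genes at 0.983 to 0.984 between VF libraries, 0.948 to 0.968 between E12 libraries, 0.844 to 0.92 between WT libraries, 0.898 to 0.93 between E12 and VF, 0.762 to 0.894 between E12 and WT, and 0.715 to 0.825 between VF and WT. Genes are not independent replicates, so these correlations carry no p-value. Hemoglobin transcripts took 3.371% of the counts in E12 5, against 0.104% and 0.079% in E12 1 and E12 2, 0.005% to 0.006% in VF and 0.173% to 0.325% in WT.

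**Figure D1:**
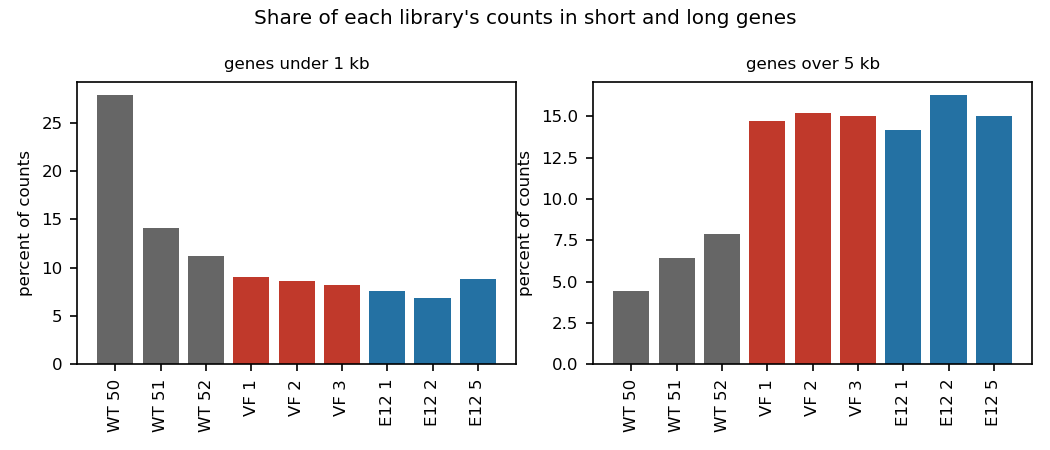
Percent of each library's counts (vertical axes) in genes shorter than 1 kb (left) and longer than 5 kb (right), one bar per library, grey for WT, red for VF and blue for E12. The WT bars lie between 11.2% and 27.9% on the left and between 4.4% and 7.9% on the right, the mutant bars between 6.9% and 9.0% and between 14.2% and 16.3%.

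VF cells had far fewer erythroid and far more megakaryocyte and stem cell transcripts than WT cells. Carbonic anhydrase Car2 was at 977 ± 154 against 15131 ± 2157 CPM and the transcription factor Fli1 at 214 ± 15.2 against 4.98 ± 2.57 CPM. Transcripts of ribosomal proteins, respiratory chain subunits and heme synthesis enzymes were lower in VF, while those of glycolysis were mixed. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6612 of 13608 genes passed an adjusted p of 0.05, 3770 higher and 2842 lower in VF. All libraries of one group lay above all of the other for 62.7% of genes, against 10% by chance. The split moved with gene length. Higher genes made up 57% of the calls but 27.8% with offsets for gene length and GC content, an alternative chosen after seeing the data, and the median log2 fold change of all tested genes moved from 0.362 to -0.54 (0.21 with RLE scaling). The median was -1.77 over the 1228 genes under 1 kb and 1.22 over the 2393 genes over 5 kb.

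Jak2 itself (Entrez gene 16452, chromosome 19, 29251803 to 29313095, GRCm38) was at 87.5 ± 4.71 against 23.9 ± 12.7 CPM, log2 fold change 1.87, SE 0.34, adjusted p = 0.0028 by edgeR. With the length and GC offsets its log2 fold change was 0.35 (adjusted p = 0.22). Its level does not check the labels, which name a changed protein and not a changed amount of transcript.

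Of 29 erythroid genes tested, 27 fell in VF and 1 rose, the same numbers when adjusted over the list alone, with a median log2 fold change of -4.44 (camera adjusted p = 3.3e-13, adjusted p = 0.18 with an estimated correlation). The Rh blood group gene Rhd was at 15.3 ± 8.64 against 2696 ± 1538 CPM, log2 fold change -7.46, SE 0.74, adjusted p = 0.00025 by edgeR. Epor, the erythropoietin receptor (chromosome 9, 21958897 to 21963576), was at 28.99 ± 5.7 against 164 ± 49.6 CPM, log2 fold change -2.5, SE 0.32, adjusted p = 0.00063. Tmem56 was at 1.79 ± 0.760 against 23.5 ± 3.68 CPM. The gene that rose, named after its value was seen, was the transcription factor Tal1 (log2 fold change 1.0), which also acts in stem cells and megakaryocytes. Heme synthesis moved the same way, with 9 of 13 genes lower and 1 higher, also over the list alone, and a median of -2.41 (camera adjusted p = 1.15e-05, adjusted p = 0.14 with an estimated correlation). Cpox, which makes protoporphyrinogen, was at 10.6 ± 2.39 against 108 ± 11.1 CPM. The gene that rose was Alas1 (log2 fold change 1.94, named after its value was seen), the form of the first enzyme found outside the red cell lineage. With the offsets the medians of both lists stayed below 0, at -4.16 and -2.9. Genes higher and lower with the offsets, then with only the 2 groups fitted, were 0 and 23 of 27, then 1 and 27, for erythroid genes and 0 and 11, then 0 and 9, for heme synthesis.

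Megakaryocyte genes went the other way. Of 25 tested, 20 rose in VF by edgeR (23 adjusted over the list alone), with a median log2 fold change of 5.01 (camera adjusted p = 8.68e-08, adjusted p = 0.13 with an estimated correlation). Itgb3 (chromosome 11, 104608000 to 104670476), the integrin chain of the platelet fibrinogen receptor, had no count in WT and 137 ± 20.8 CPM in VF, at least 3644-fold higher when WT is set to 3 counts over the group. The caveolae protein gene Cavin2 was at 131 ± 15.9 against 0.103 ± 0.0374 CPM and Fli1 (chromosome 9, 32422204 to 32543432) had a log2 fold change of 5.42 (SE 0.41, adjusted p = 0.00012). Intervals and floors of this kind cover counting error only.

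Stem and multipotent progenitor genes rose with them, 13 of 17 higher and 1 lower (14 and 1 adjusted over the list alone), with a median log2 fold change of 3.32 (camera adjusted p = 7.46e-05, adjusted p = 0.15 with an estimated correlation). The surface marker Cd34 was at 660 ± 23.2 against 3.63 ± 1.17 CPM, log2 fold change 7.51, SE 0.47, adjusted p = 6.7e-05 by edgeR. Meis1, a homeobox factor of stem cells, was at 266 ± 12.2 against 8.21 ± 3.14 CPM, and Angpt1, a ligand of the receptor Tek, at 261 ± 24.6 against 9.92 ± 3.91 CPM. Tek itself had no count in WT and was at least 1480-fold higher in VF. The gene that fell was Mllt3 (log2 fold change -2.23, named after its value was seen). With the offsets, then with the 2 groups alone, the higher and lower calls were 19 and 0, then 19 and 0, for megakaryocyte genes and 12 and 1, then 12 and 1, for stem cell genes.

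Some genes of other lineages were higher in VF too. Of 20 neutrophil genes 9 rose by edgeR, also over the list alone, with a median log2 fold change of 0.35 (camera adjusted p = 0.307), and with the offsets the list passed upward (0.0004). Mpo, the peroxidase of neutrophil granules, was at 6888 ± 2076 against 129 ± 84.3 CPM, and the receptor Csf3r at 79.6 ± 5.21 against 7.0 ± 2.65 CPM. Of 12 genes of mast cells, basophils and eosinophils 6 rose (median 2.92, camera adjusted p = 0.0236, adjusted p = 0.36 with an estimated correlation), and without WT 52 the list's adjusted p was 0.12. The IgE receptor chain Fcer1a had 1 count in WT and 3751 in VF, a ratio of 3822 (686 to 150999) with its 95% counting interval. Of 19 monocyte genes 7 rose (median 1.56, camera adjusted p = 0.0767), and the adjusted p was 0.016 without WT 50, 0.0064 without WT 50 and E12 5 and 0.00041 with the offsets. Of 12 B cell genes 3 fell, Vpreb1, Vpreb3 and Igll1, genes of B cell precursors, and 0 passed when adjusted over the list alone, with 5 at an unadjusted p under 0.05, 6 by DESeq2 and 1 higher and 5 lower by limma-voom (camera adjusted p = 0.166). Igll1 was at 42.3 ± 22.8 against 677 ± 839 CPM, adjusted p = 0.045 by edgeR. The calls of the 3 genes were lost without VF 1, VF 2, VF 3 or WT 50, and that of Igll1 also without E12 1, with adjusted p from 0.051 to 0.13. Under the offsets and then in the fit of the 2 groups, genes higher and lower numbered 9 and 0, then 8 and 0, for neutrophil genes, 7 and 0, then 6 and 0, for mast cell genes, 8 and 0, then 6 and 0, for monocyte genes and 1 and 1, then 0 and 5, for B cell genes.

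Among the metabolic lists, the respiratory chain moved one way. Of 36 complex I subunit genes 34 fell in VF (35 over the list alone), with a median log2 fold change of -2.59 (camera adjusted p = 1.15e-12, adjusted p = 0.36 with an estimated correlation). Ndufv1, a core subunit, was at 207 ± 10.2 against 735 ± 131 CPM, log2 fold change -1.83, SE 0.25, adjusted p = 0.00081 by edgeR. On the deposited levels its call was lost, with adjusted p = 0.13 by limma. Of 35 genes of complexes III to V, 33 fell (34 over the list alone), median -2.57 (camera adjusted p = 1.11e-12, adjusted p = 0.36 with an estimated correlation). Cytochrome c1, Cyc1, was at 260 ± 15.3 against 1625 ± 760 CPM and Uqcrc1 at 919 ± 5.04 against 5517 ± 2127 CPM. Of 65 cytosolic ribosomal protein genes 62 fell (65 over the list alone), median -2.11 (camera adjusted p = 7.24e-17, adjusted p = 0.42 with an estimated correlation). In these 3 lists 0 genes rose by edgeR, DESeq2 or limma-voom, and 0 were higher at an unadjusted p under 0.05. Rpl4 was at 1712 ± 93.3 against 5603 ± 1181 CPM, and its log2 fold change was -0.15 on the deposited levels (adjusted p = 0.73 by limma). These are mostly short transcripts, of which the WT libraries held the larger share. Without WT 50 the medians of the 3 lists were -1.75, -1.66 and -1.4, and with the offsets -1.32, -1.08 and -0.75, against -0.54 for all genes. Calls higher and lower, first with the offsets and then with the 2 groups alone, were 1 and 32, then 0 and 33, for complex I, 0 and 32, then 0 and 32, for complexes III to V and 2 and 46, then 0 and 53, for ribosomal proteins.

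Enzymes of the mitochondrial matrix fell in part. In the list of pyruvate dehydrogenase and the tricarboxylic acid cycle 9 of 21 genes fell, also over the list alone, with a median of -1.3 (camera adjusted p = 3.02e-04, adjusted p = 0.15 with an estimated correlation). Pdhb was at 214 ± 2.94 against 984 ± 197 CPM, log2 fold change -2.2, SE 0.26, adjusted p = 0.00049 by edgeR. In fatty acid oxidation 8 of 20 fell and 1 rose, also over the list alone, with a median of -0.6 (camera adjusted p = 0.00996, adjusted p = 0.25 with an estimated correlation), and with the offsets the list's adjusted p was 0.054. The thiolase Acaa2 was at 135 ± 3.87 against 773 ± 163 CPM, and the gene that rose was Cpt1a (log2 fold change 0.84, named after its value was seen), which lets fatty acids into mitochondria. Of 20 glutathione and antioxidant enzymes 14 fell and 3 rose (15 and 3 over the list alone), median -1.51 (camera adjusted p = 4.43e-04, adjusted p = 0.17 with an estimated correlation). Mitochondrial Txnrd2 was at 41.7 ± 2.55 against 259 ± 76.3 CPM and Prdx3 at 145 ± 5.13 against 582 ± 22.4 CPM. The 3 that rose, named after their values were seen, were Gclm, Gsr and Txnrd1 (log2 fold changes 2.0, 2.56 and 1.78). In the fit with the offsets, then in that of the 2 groups, higher and lower calls were 0 and 20, then 0 and 9, for the tricarboxylic acid cycle list, 0 and 10, then 1 and 5, for fatty acid oxidation and 3 and 13, then 3 and 13, for antioxidant enzymes.

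Glycolysis genes did not move one way. Of 25 tested, 6 rose and 6 fell, also over the list alone, with a median log2 fold change of 0.39 and a mean of 0.62. The list did not stand apart from other genes (camera adjusted p = 0.777). Hk3, a hexokinase of white blood cells, was at 122 ± 13.5 against 0.301 ± 0.272 CPM, and Pkm, the pyruvate kinase of most tissues, at 630 ± 38.7 against 43.5 ± 17.2 CPM, log2 fold change 3.86, SE 0.39, adjusted p = 0.00027 by edgeR. The enolase Eno3 was lower, at 8.64 ± 0.623 against 48.4 ± 7.53 CPM. Pfkfb3, which raises the flow through glycolysis, was at 23.6 ± 2.47 against 1.44 ± 1.33 CPM (adjusted p = 0.0098) and Hk2 at 32.97 ± 2.17 against 8.71 ± 5.17 CPM (adjusted p = 0.0077), but the call of Hk2 was lost without WT 51 (adjusted p = 0.057) and with the offsets (log2 fold change 0.19, adjusted p = 0.77). Lactate dehydrogenase Ldha was at 1213 ± 19.9 against 1755 ± 379 CPM (log2 fold change -0.53, adjusted p = 0.14). Among 10 transporters of glucose, lactate and pyruvate 3 rose and 4 fell, also over the list alone, with a median of 0.75 but a downward test (camera adjusted p = 0.823). The glucose transporter Slc2a1 was at 39 ± 2.06 against 2.25 ± 1.93 CPM, log2 fold change 4.09, SE 0.93, adjusted p = 0.0067 by edgeR, and the mitochondrial pyruvate carrier gene Mpc1 at 54.4 ± 1.84 against 304 ± 268 CPM. Genes higher and lower with the offsets, then with only the 2 groups fitted, were 4 and 9, then 5 and 5, for glycolysis and 1 and 4, then 2 and 2, for the transporters.

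Cholesterol synthesis genes were split as well. Of 24 tested 5 rose and 5 fell, also over the list alone (median 0.31, camera adjusted p = 0.884). Hmgcs1, early in the pathway, rose and was at 55.8 ± 1.67 against 6.14 ± 0.916 CPM, log2 fold change 3.18, SE 0.24, adjusted p = 0.00012 by edgeR. In fatty acid synthesis 3 of 15 rose and 4 fell, also over the list alone, and the citrate lyase Acly was at 280 ± 15.3 against 70.3 ± 29.2 CPM. That list had a median of 0.46, a mean of -0.02 and a downward test (camera adjusted p = 0.744). In iron handling 3 of 14 rose and 5 fell, also over the list alone (median -0.4, camera adjusted p = 0.207). Ncoa4, the receptor that takes ferritin to lysosomes, was at 162 ± 9.45 against 14.3 ± 7.88 CPM, and the ferritin heavy chain Fth1 at 827 ± 54.4 against 7388 ± 6498 CPM. With the offsets, then with the 2 groups alone, the higher and lower calls were 4 and 10, then 5 and 4, for cholesterol synthesis, 1 and 8, then 2 and 3, for fatty acid synthesis and 2 and 9, then 3 and 4, for iron handling.

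Cell cycle genes were mostly lower where they differed. Of 25 S phase genes 10 fell and 1 rose, also over the list alone (median -0.78, camera adjusted p = 0.00996, adjusted p = 0.36 with an estimated correlation), and of 27 G2 and M phase genes 10 fell and 2 rose (9 and 2 over the list alone; median -0.51, camera adjusted p = 0.0169, adjusted p = 0.5 with an estimated correlation). Without WT 52 the lists' adjusted p were 0.071 and 0.11. Pcna was at 180 ± 7.61 against 844 ± 339 CPM and Cdk1 at 129 ± 10.8 against 680 ± 456 CPM. Those that rose, named after their values were seen, were Dtl, Bub1 and Kif11 (log2 fold changes 1.53, 0.74 and 1.29). In nucleotide synthesis 10 of 19 fell and 1 rose, also over the list alone (median -0.89, camera adjusted p = 0.00178, adjusted p = 0.23 with an estimated correlation). Umps, the last enzyme of uridine monophosphate synthesis, was at 272 ± 9.32 against 1034 ± 333 CPM, and Impdh1 rose, at 57.6 ± 7.51 against 20.9 ± 2.41 CPM, a call lost with the offsets (log2 fold change 0.26, adjusted p = 0.22). Under the offsets and then in the fit of the 2 groups, genes higher and lower numbered 0 and 19, then 1 and 7, for the S phase, 0 and 22, then 2 and 6, for the G2 and M phase and 0 and 15, then 1 and 8, for nucleotide synthesis.

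Of 17 JAK-STAT5 target genes 7 rose by edgeR, also over the list alone, with a median log2 fold change of 1.99. The list missed the threshold (camera adjusted p = 0.0702) but passed it without WT 51 (0.041) and with the offsets (0.04). The feedback inhibitor Socs2 was at 27.96 ± 0.463 against 4.44 ± 2.46 CPM, log2 fold change 2.65, SE 0.49, adjusted p = 0.0027 by edgeR. Socs3 had no count in WT and was at least 252-fold higher in VF. The kinases Pim1 and Pim2 were at 10.7 ± 0.938 against 0.611 ± 0.622 CPM and 58.5 ± 18.9 against 14.7 ± 4.01 CPM. Cish, a classical STAT5 target, was at 16.3 ± 2.51 against 4.0 ± 6.05 CPM (log2 fold change 2.01, SE 1.29, adjusted p = 0.22). Of 19 immediate early genes 12 rose and 1 fell, also over the list alone, with a median of 2.64, or 1.78 with genes at 0 set to their bound (camera adjusted p = 0.0589). That list passed without VF 3 (0.017), E12 1 (0.048) or WT 50 (0.038), without a filter (0.031) and with the offsets (0.016). Egr1 was at 36.8 ± 16.8 against 3.67 ± 0.838 CPM. Calls higher and lower, first with the offsets and then with the 2 groups alone, were 6 and 3, then 6 and 0, for JAK-STAT5 targets and 9 and 3, then 11 and 0, for immediate early genes.

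E12 cells shared the higher megakaryocyte and stem cell transcripts and the lower respiratory and ribosomal transcripts with VF cells, but their erythroid genes lay on both sides of WT. Cd34 was at 211 ± 85.2 against 3.63 ± 1.17 CPM and Itgb3 at 19.2 ± 2.34 CPM against no count. The transferrin receptor gene Tfrc, through which red cell precursors take up iron, was at 1208 ± 412 against 118 ± 27.5 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 5717 genes passed, 3251 higher and 2466 lower in E12. The count was 3618 without E12 2 and 2934 when only the libraries of the 2 groups were fitted. Higher genes made up 56.9% of the calls, or 28.2% with the length and GC offsets, and the median of all genes moved from 0.355 to -0.371 (0.168 with RLE scaling). Groups did not overlap for 53.3% of genes, against 10% by chance.

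Of 29 erythroid genes 5 rose and 9 fell in E12, also over the list alone. The median log2 fold change was 0.4 and the mean 0.3, while the test against all other genes pointed down (camera adjusted p = 0.0795), and with the offsets the median was -0.45. Without E12 5, the library rich in hemoglobin, the downward test passed (0.0035). Tmem56 was at 81.1 ± 11.5 against 23.5 ± 3.68 CPM, log2 fold change 1.79, SE 0.34, adjusted p = 0.0049 by edgeR, and Tal1 at 159 ± 9.79 against 51.8 ± 5.16 CPM, calls that were lost with the offsets (adjusted p = 0.62 and 0.31). Rhd was lower, at 302 ± 103 against 2696 ± 1538 CPM. Epor was at 141 ± 29.4 against 164 ± 49.6 CPM (log2 fold change -0.22, adjusted p = 0.58). In heme synthesis 6 of 13 fell and 1 rose (7 and 1 over the list alone), median -0.79 (camera adjusted p = 0.0388, adjusted p = 0.36 with an estimated correlation). That list missed the threshold without E12 2 (0.073), WT 51 (0.059) or WT 52 (0.1) and with the offsets (0.051). Urod was at 238 ± 40.2 against 1284 ± 846 CPM, and Abcb10, a mitochondrial transporter, rose (log2 fold change 1.36, named after its value was seen). In iron handling 5 of 14 rose and 2 fell (6 and 2 over the list alone), median 0.57 (camera adjusted p = 0.307), or -0.3 with the offsets. In the fit with the offsets, then in that of the 2 groups, higher and lower calls were 3 and 7 of 27, then 5 and 8, for erythroid genes, 0 and 6, then 1 and 4, for heme synthesis and 3 and 4, then 4 and 1, for iron handling.

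Of 25 megakaryocyte genes 14 rose and 1 fell, also over the list alone, with a median log2 fold change of 2.97 (camera adjusted p = 1.15e-04, adjusted p = 0.14 with an estimated correlation). Cavin2 was at 20.9 ± 4.61 against 0.103 ± 0.0374 CPM, log2 fold change 7.63, SE 0.38, adjusted p = 8.8e-05 by edgeR, and Fli1 at 55.6 ± 3.98 against 4.98 ± 2.57 CPM. Itgb3 was at least 509-fold higher. The gene that fell was Myl9, a myosin light chain (log2 fold change -5.26, named after its value was seen). Of 17 stem and multipotent progenitor genes 11 rose (11 higher and 1 lower over the list alone), median 1.8 (camera adjusted p = 6.43e-04, adjusted p = 0.18 with an estimated correlation). Meis1 was at 64.5 ± 11.3 against 8.21 ± 3.14 CPM, and Mecom, without a count in WT, was at least 97.5-fold higher. Of 20 neutrophil genes 3 rose and 4 fell (3 and 3 over the list alone; median -0.56, camera adjusted p = 0.566), Mpo among those that rose, at 1446 ± 466 against 129 ± 84.3 CPM. Of 19 monocyte genes 5 rose (median 1.92, camera adjusted p = 0.207, 0.036 without WT 50 and 0.0018 with the offsets), and of 12 mast cell, basophil and eosinophil genes 4 rose and 1 fell (median 1.52, camera adjusted p = 0.349, and 0.0075 with the offsets). Of 11 T and NK cell genes 1 fell, Cd2, and 0 passed over the list alone, 1 at an unadjusted p under 0.05, 2 by DESeq2 and 1 by limma-voom (median -1.48, camera adjusted p = 0.0165, adjusted p = 0.49 with an estimated correlation). Its adjusted p was 0.12 without WT 50, 0.064 without WT 51 and 0.31 with the offsets. Without WT 50 and E12 5, 8 fell (median -2.42). The call of Cd2 was lost without VF 1, VF 2, VF 3, E12 1, E12 2 or WT 50 (0.063 to 0.12). Genes higher and lower with the offsets, then with the 2 groups alone, were 14 and 0, then 13 and 0, for megakaryocyte genes. They were 9 and 1, then 7 and 0, for stem cell genes. For neutrophil and for monocyte genes they were 4 and 0, then 3 and 0, for mast cell genes 3 and 0, then 1 and 0. For T and NK cell genes they were 0 in both.

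Respiratory chain and ribosomal protein genes were lower in E12 than in WT, as in VF. Of 36 complex I genes 35 fell, also over the list alone (median -2.49, camera adjusted p = 1.31e-13, adjusted p = 0.36 with an estimated correlation), and of 35 genes of complexes III to V 33 fell, also over the list alone (median -2.31, camera adjusted p = 1.28e-12, adjusted p = 0.36 with an estimated correlation). Of 65 ribosomal protein genes 62 fell (63 over the list alone; median -1.94, camera adjusted p = 1.29e-18, adjusted p = 0.39 with an estimated correlation). Uqcrc1 was at 1209 ± 290 against 5517 ± 2127 CPM, log2 fold change -2.19, SE 0.37, adjusted p = 0.0033 by edgeR, Rpl35 at 260 ± 35.2 against 2614 ± 2430 CPM and Rpl3 at 325 ± 26.04 against 1012 ± 369 CPM. The call of Rpl3 was lost on the deposited levels (adjusted p = 0.073 by limma). Without WT 50 the medians were -1.56, -1.41 and -1.2, and with the offsets -0.93, -0.63 and -0.46, against -0.37 for all genes. In the list of pyruvate dehydrogenase and the tricarboxylic acid cycle 9 of 21 fell and 1 rose, also over the list alone (median -0.39, camera adjusted p = 0.0107, adjusted p = 0.22 with an estimated correlation), and without WT 52 the list's adjusted p was 0.1. Mdh2 was at 1041 ± 223 against 6688 ± 4680 CPM, and the gene that rose was Ogdh (log2 fold change 0.83, named after its value was seen). In fatty acid oxidation 8 of 20 fell, also over the list alone (median -0.64, camera adjusted p = 0.00425, adjusted p = 0.23 with an estimated correlation). With the offsets, then with the 2 groups alone, the higher and lower calls were 0 and 25, then 0 and 29, for complex I, 0 and 22, then 0 and 19, for complexes III to V, 1 and 28, then 0 and 30, for ribosomal proteins, 0 and 10, then 0 and 6, for the tricarboxylic acid cycle list and 0 and 11, then 0 and 6, for fatty acid oxidation.

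Glycolysis was again mixed, with 5 of 25 genes higher and 4 lower (7 and 6 over the list alone), a median log2 fold change of 0.19 and a downward test (camera adjusted p = 0.903). Pkm was at 210 ± 57.4 against 43.5 ± 17.2 CPM, log2 fold change 2.27, SE 0.36, adjusted p = 0.0027 by edgeR, and Hk3 at 42.8 ± 16.2 against 0.301 ± 0.272 CPM. Slc2a1 was at 12.99 ± 3.05 against 2.25 ± 1.93 CPM (adjusted p = 0.044), a call that was lost without VF 1, VF 2, VF 3, E12 1, E12 2, E12 5 or WT 52 (0.063 to 0.11) and with the offsets (0.076). Pfkfb3 was at 16.4 ± 2.08 against 1.44 ± 1.33 CPM (adjusted p = 0.019), lost without E12 2 (0.057) and with the offsets (0.073). Ldha was at 1762 ± 116 against 1755 ± 379 CPM (log2 fold change 0.01, adjusted p = 0.99), and Hk2 at 20 ± 6.18 against 8.71 ± 5.17 CPM (adjusted p = 0.054). Among 20 glutathione and antioxidant enzymes 11 fell and 3 rose (13 and 3 over the list alone; median -0.93, camera adjusted p = 0.0112, adjusted p = 0.23 with an estimated correlation), and with the offsets the list's adjusted p was 0.17. The 3 that rose were Gclm at 279 ± 39.6 against 36.5 ± 7.34 CPM, log2 fold change 2.94, SE 0.25, adjusted p = 0.00044 by edgeR, Txnrd1 at 145 ± 12.4 against 27.6 ± 7.25 CPM and Gsr at 102 ± 6.95 against 15.3 ± 7.71 CPM, which supply and recycle glutathione and thioredoxin. Hmgcs1 was at 36.1 ± 4.72 against 6.14 ± 0.916 CPM and Acly at 359 ± 30.4 against 70.3 ± 29.2 CPM. Cholesterol synthesis had 5 of 24 higher and 4 lower (5 and 3 over the list alone; median 0.56, camera adjusted p = 0.682), and fatty acid synthesis 4 of 15 higher and 1 lower, also over the list alone (median 0.45, camera adjusted p = 0.548). With the offsets the medians of these 2 lists were -0.45 and -0.6. Under the offsets and then in the fit of the 2 groups, genes higher and lower numbered 3 and 6, then 3 and 1, for glycolysis, 3 and 12, then 3 and 3, for antioxidant enzymes, 4 and 8, then 5 and 3, for cholesterol synthesis and 1 and 6, then 3 and 0, for fatty acid synthesis.

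Immediate early genes rose in E12, 14 of 19 by edgeR (15 over the list alone), with a median log2 fold change of 2.24 (camera adjusted p = 0.00306, adjusted p = 0.23 with an estimated correlation). Fos was at 216 ± 81.6 against 8.23 ± 3.99 CPM, log2 fold change 4.71, SE 0.78, adjusted p = 0.0031 by edgeR, and Egr1 at 57.97 ± 21.8 against 3.67 ± 0.838 CPM. Of 15 p53 target genes 9 rose and 1 fell, also over the list alone (median 2.11, camera adjusted p = 0.0177, adjusted p = 0.18 with an estimated correlation), and without WT 52 the list's adjusted p was 0.079. The cyclin Ccng1 was at 198 ± 40.02 against 30.9 ± 4.5 CPM, log2 fold change 2.67, SE 0.25, adjusted p = 0.00053, and Phlda3 at 24.9 ± 12.2 against 2.02 ± 1.35 CPM. The gene that fell was Bax (log2 fold change -1.95, named after its value was seen), which promotes cell death. Of 17 JAK-STAT5 target genes 5 rose, also over the list alone (median 1.5, camera adjusted p = 0.0766, 0.037 without WT 51 and 0.029 with the offsets). Socs3 was at least 101-fold higher, Socs1 at 7.15 ± 2.19 against 0.211 ± 0.243 CPM and Pim1 at 6.91 ± 2.11 against 0.611 ± 0.622 CPM, a call lost without WT 51 (0.058). Jak2 was at 38.9 ± 2.65 against 23.9 ± 12.7 CPM (log2 fold change 0.7, SE 0.33, adjusted p = 0.12), Cish at 25.6 ± 9.48 against 4.0 ± 6.05 CPM (0.13) and Socs2 at 8.5 ± 3.73 against 4.44 ± 2.46 CPM (0.13). Calls higher and lower, first with the offsets and then with the 2 groups alone, were 11 and 0, then 9 and 0, for immediate early genes, 5 and 2, then 4 and 0, for p53 targets and 4 and 4, then 4 and 0, for JAK-STAT5 targets.

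The mutant groups were compared with WT through the same 3 WT libraries. Of the genes called in both comparisons 4791 moved the same way, 2685 higher and 2106 lower, and 19 moved in opposite directions. Independent lists of these sizes would share 901 and 515. In 20 simulations all 9 libraries, WT included, were drawn anew around the WT means, and at most 0 genes were called the same way. No group difference was drawn, so next to no calls followed from the construction, and this count is no measure for the 4791. The log2 fold changes correlated across genes at r = 0.91, against 0.474 to 0.519 in the simulations, with a covariance of 5.59 against 0.376, a difference of 5.21. The 3 WT libraries are too few to split, so part of the excess may come from the shared controls. Without E12 2 the same-way count was 3186, and with only the libraries of each pair of groups fitted it was 2475. Echdc2 (chromosome 4, 108165436 to 108179308), a mitochondrial enzyme gene, had no count in WT and was at least 4248-fold higher in VF and 1645-fold in E12. Sirpa, which codes for the receptor of Cd47 on myeloid cells, was at least 680-fold and 448-fold higher, and Tek at least 1480-fold and 413-fold. Spon2, a secreted matrix protein gene, was lower in both, at 2.72 ± 1.0 CPM in VF and 9.15 ± 2.85 in E12 against 256 ± 44.6 in WT.

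**Figure D2:**
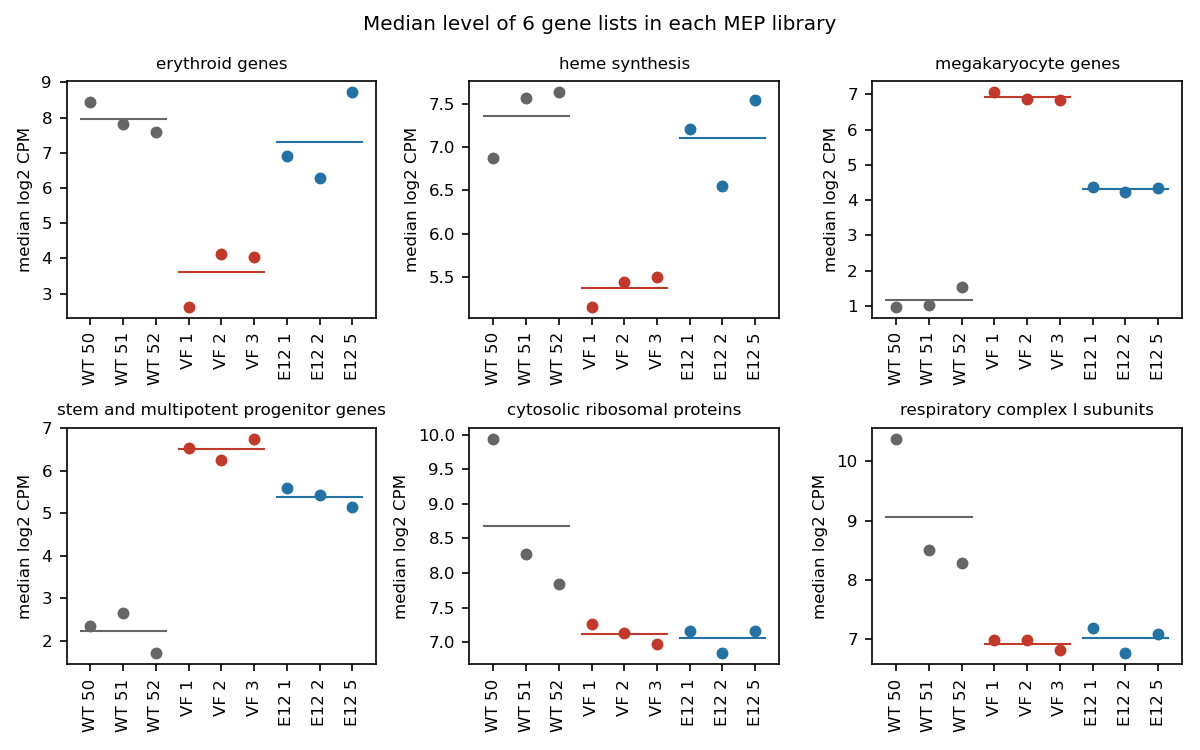
Median log2 CPM (vertical axes) of the tested members of 6 gene lists in each library (points), with the mean of each group (lines), grey for WT, red for VF and blue for E12. Erythroid genes are lowest in VF, megakaryocyte and stem cell genes are lowest in WT, and ribosomal protein and complex I genes are highest in WT.

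Erythroid transcripts were higher and megakaryocyte and stem cell transcripts lower in E12 than in VF. Tfrc was at 1208 ± 412 against 75.3 ± 2.01 CPM and Cavin2 at 20.9 ± 4.61 against 131 ± 15.9 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 437 genes passed, 298 higher and 139 lower in E12, with 2415 at an unadjusted p under 0.05, and groups did not overlap for 59.5% of genes, against 10% by chance. The count depends on WT, whose libraries vary most and share 1 fitted spread with E12 and VF. It was 6422 when only the E12 and VF libraries were fitted, and all 437 genes were among them. It was 3301 without WT 50, 1284 without WT 52 and 720 without WT 51, but 40, 58 and 19 without VF 1, VF 2 and VF 3, and 45, 114 and 78 without E12 1, E12 2 and E12 5. The median log2 fold change was -0.03 under 1 kb and -0.16 over 5 kb, and that of all genes was -0.046, -0.089 with RLE scaling and 0.133 with the offsets.

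Of 29 erythroid genes 24 rose in E12 by edgeR (28 over the list alone), with a median log2 fold change of 4.3 (camera adjusted p = 4.38e-26, adjusted p = 0.14 with an estimated correlation). Tmem56 was at 81.1 ± 11.5 against 1.79 ± 0.760 CPM, log2 fold change 5.5, SE 0.4, adjusted p = 0.0017, a call that no left-out library ended. The membrane skeleton genes Ank1 and Sptb were at 42.1 ± 4.99 against 1.36 ± 0.969 CPM and 55.9 ± 20.9 against 3.85 ± 0.570 CPM, with adjusted p = 0.0046 and 0.006. Ank1 missed the threshold without VF 3 (0.055), and Sptb without VF 1 or VF 3 (0.057 to 0.063). Epor was at 141 ± 29.4 against 28.99 ± 5.7 CPM, log2 fold change 2.28, SE 0.32, adjusted p = 0.011, and missed the threshold without VF 1, VF 2, VF 3 or E12 1 (0.053 to 0.097). The hemoglobin genes had the largest fold changes, and reads of Hba-a1 and Hba-a2, of Hbb-b1 and Hbb-bs and of Hbb-bt and Hbb-b2 cannot be assigned with certainty between the near-identical copies. Hba-a1 was at 3205 ± 5049 against 15.4 ± 3.16 CPM (adjusted p = 0.037), with 9034 CPM in E12 5 against 339 and 242 in E12 1 and E12 2. Its call was lost without VF 1, VF 2, VF 3 or E12 1 (0.074 to 0.19). In the fit with the offsets, then in that of the 2 groups, higher and lower calls were 25 and 0 of 27, then 29 and 0, for erythroid genes.

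Heme and iron genes moved with them. Of 13 heme synthesis genes 5 rose by edgeR (12 higher and 1 lower over the list alone), median 1.63 (camera adjusted p = 2.77e-08, adjusted p = 0.14 with an estimated correlation). Cpox was at 157 ± 56.4 against 10.6 ± 2.39 CPM, log2 fold change 3.89, SE 0.33, adjusted p = 0.0017. Abcb6, a porphyrin transporter, was at 102 ± 16.6 against 19.3 ± 2.58 CPM (adjusted p = 0.014) and Slc25a38, which carries glycine for heme synthesis, at 106 ± 13 against 26.5 ± 5.76 CPM (0.015). Both calls were lost without VF 1, VF 2, VF 3, E12 1 or E12 5 (0.063 to 0.12). Of 14 iron handling genes 4 rose (6 higher and 1 lower over the list alone), median 1.03 (camera adjusted p = 1.54e-04, adjusted p = 0.14 with an estimated correlation). Tfrc had a log2 fold change of 4.0 (SE 0.36, adjusted p = 0.0018). The endosomal reductase Steap3 was at 241 ± 27.5 against 39 ± 8.03 CPM and the iron exporter Slc40a1 at 92.2 ± 19.1 against 10.6 ± 3.4 CPM, calls lost without any 1 of the VF or E12 libraries (0.063 to 0.15). Genes higher and lower with the offsets, then with only the 2 groups fitted, were 9 and 0, then 12 and 1, for heme synthesis and 6 and 0, then 9 and 2, for iron handling.

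Megakaryocyte genes fell, 9 of 25 by edgeR (16 over the list alone), with a median log2 fold change of -2.36 (camera adjusted p = 7.34e-12, adjusted p = 0.08 with an estimated correlation). Cavin2 had a log2 fold change of -2.64 (SE 0.27, adjusted p = 0.0035). Itgb3 was at 19.2 ± 2.34 against 137 ± 20.8 CPM (adjusted p = 0.0046, and 0.055 without VF 3), and Vwf, the von Willebrand factor, at 25.4 ± 7.25 against 122 ± 11.9 CPM (adjusted p = 0.018). Of 17 stem and multipotent progenitor genes 5 fell and 1 rose (9 and 1 over the list alone), median -1.65 (camera adjusted p = 1.7e-05, adjusted p = 0.14 with an estimated correlation). Meis1 was at 64.5 ± 11.3 against 266 ± 12.2 CPM and the gene that rose, Mllt3, at 48.4 ± 5.67 against 16.8 ± 2.5 CPM. Of 20 neutrophil genes 2 fell (6 over the list alone), median -1.29 (camera adjusted p = 1.49e-04, adjusted p = 0.39 with an estimated correlation). Elane, the neutrophil elastase, was at 56.1 ± 7.15 against 974 ± 527 CPM, and Ms4a3 at 20 ± 13.5 against 186 ± 53.8 CPM. The calls of Vwf, Meis1, Mllt3, Elane and Ms4a3 were lost without any 1 of the VF or E12 libraries, and that of Ms4a3 also without WT 51 (0.055 to 0.21). Of 12 mast cell, basophil and eosinophil genes 1 fell, also over the list alone, Fcer1a, at 8.2 ± 5.17 against 48 ± 3.21 CPM (list median -2.14, camera adjusted p = 5.78e-04, adjusted p = 0.22 with an estimated correlation), and its call was lost in the same way (0.072 to 0.21). With the offsets, then with the 2 groups alone, the higher and lower calls were 0 and 10, then 0 and 23, for megakaryocyte genes, 1 and 6, then 1 and 15, for stem cell genes, 0 and 6, then 0 and 9, for neutrophil genes and 0 and 1, then 0 and 6, for mast cell genes.

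Among metabolic genes the pyruvate kinases moved apart. Pklr, the form of liver and red cells, was at 97.05 ± 19.2 against 4.05 ± 1.89 CPM, log2 fold change 4.58, SE 0.58, adjusted p = 0.0069 by edgeR, and missed the threshold without VF 1 or VF 3 (0.056 to 0.071). Pkm was at 210 ± 57.4 against 630 ± 38.7 CPM, log2 fold change -1.59, SE 0.36, adjusted p = 0.049, and missed it without any 1 of the VF or E12 libraries (0.1 to 0.21). They were the only called members of the glycolysis list (3 higher and 1 lower over the list alone), whose median was -0.2 and mean -0.07 while its test pointed up (camera adjusted p = 0.777). In serine and one-carbon metabolism 2 of 10 rose (3 over the list alone), median 0.61 (camera adjusted p = 0.0036, adjusted p = 0.22 with an estimated correlation). Mthfd2 was at 147 ± 15.8 against 35.9 ± 1.33 CPM (adjusted p = 0.0046, and 0.057 without VF 3) and Mthfd1 at 717 ± 66.4 against 140 ± 12.7 CPM (adjusted p = 0.042). In nucleotide synthesis 1 of 19 rose (2 over the list alone), median 0.6 (camera adjusted p = 7.46e-05, adjusted p = 0.18 with an estimated correlation). That gene was Cad, the start of pyrimidine synthesis, at 222 ± 19.4 against 90.8 ± 2.17 CPM (adjusted p = 0.018). Of 20 antioxidant genes 2 rose, Txnrd2 at 128 ± 24.3 against 41.7 ± 2.55 CPM and Prdx3 at 354 ± 48.4 against 145 ± 5.13 CPM (8 over the list alone; list median 0.64, camera adjusted p = 7.46e-05, adjusted p = 0.14 with an estimated correlation). The calls of Mthfd1, Cad, Txnrd2 and Prdx3 were lost without any 1 of the VF or E12 libraries (0.053 to 0.21). Under the offsets and then in the fit of the 2 groups, genes higher and lower numbered 6 and 2, then 7 and 8, for glycolysis, 3 and 0, then 8 and 1, for serine and one-carbon metabolism, 5 and 0, then 15 and 0, for nucleotide synthesis and 9 and 1, then 12 and 1, for antioxidant enzymes.

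In the list of pyruvate dehydrogenase and the tricarboxylic acid cycle 0 of 21 genes passed by edgeR, over all genes or over the list alone, against 2 higher and 1 lower at an unadjusted p under 0.05 and by DESeq2 and 0 by limma-voom, and the list stood above other genes (median 0.5, camera adjusted p = 0.00282, adjusted p = 0.18 with an estimated correlation). Citrate synthase, Cs, was at 467 ± 24.9 against 189 ± 7.29 CPM (adjusted p = 0.086). For complexes III to V 0 of 35 passed by edgeR (4 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom) and the list median was 0.29 (camera adjusted p = 0.0205, adjusted p = 0.76 with an estimated correlation, and 0.051 without E12 1), and for complex I 0 of 36 passed (1 at an unadjusted p under 0.05, 0 by DESeq2 or limma-voom), median 0.15 (camera adjusted p = 0.207, and 0.021 with the offsets). Of 65 ribosomal protein genes 0 passed by edgeR (1 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom), median 0.14 (camera adjusted p = 0.207, and 0.024 with the offsets). Of 25 S phase genes 1 rose (2 over the list alone), median 0.56 (camera adjusted p = 2.36e-04, adjusted p = 0.22 with an estimated correlation). It was Ccne1, cyclin E1, at 274 ± 30.9 against 32.02 ± 5.55 CPM (adjusted p = 0.011, lost without VF 1, VF 2, VF 3 or E12 1, 0.058 to 0.097). Of 27 G2 and M phase genes 2 rose (3 over the list alone), median 0.63 (camera adjusted p = 1.02e-05, adjusted p = 0.23 with an estimated correlation). They were Ccna2 at 478 ± 94.7 against 190 ± 7.6 CPM and Hmmr at 135 ± 21.1 against 61.1 ± 2.7 CPM, both lost without any 1 of the VF or E12 libraries (0.088 to 0.22). Of 17 JAK-STAT5 target genes 1 rose (1 higher and 2 lower over the list alone; median -0.46, camera adjusted p = 0.464). It was Erfe, the erythroblast hormone that lowers hepcidin, at 22.6 ± 5.8 against 1.34 ± 0.364 CPM (adjusted p = 0.034, lost without any 1 of the VF or E12 libraries, 0.089 to 0.19). Jak2 was at 38.9 ± 2.65 against 87.5 ± 4.71 CPM (log2 fold change -1.17, adjusted p = 0.1, and 8.9e-05 with the 2 groups alone). Calls higher and lower, first with the offsets and then with the 2 groups alone, were 8 and 0, then 17 and 1, for the tricarboxylic acid cycle list, 9 and 0, then 17 and 1, for complexes III to V, 3 and 0, then 13 and 2, for complex I, 5 and 0, then 15 and 6, for ribosomal proteins, 6 and 0, then 21 and 0, for the S phase, 10 and 0, then 23 and 0, for the G2 and M phase and 1 and 1, then 2 and 6, for JAK-STAT5 targets.

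**Figure D3:**
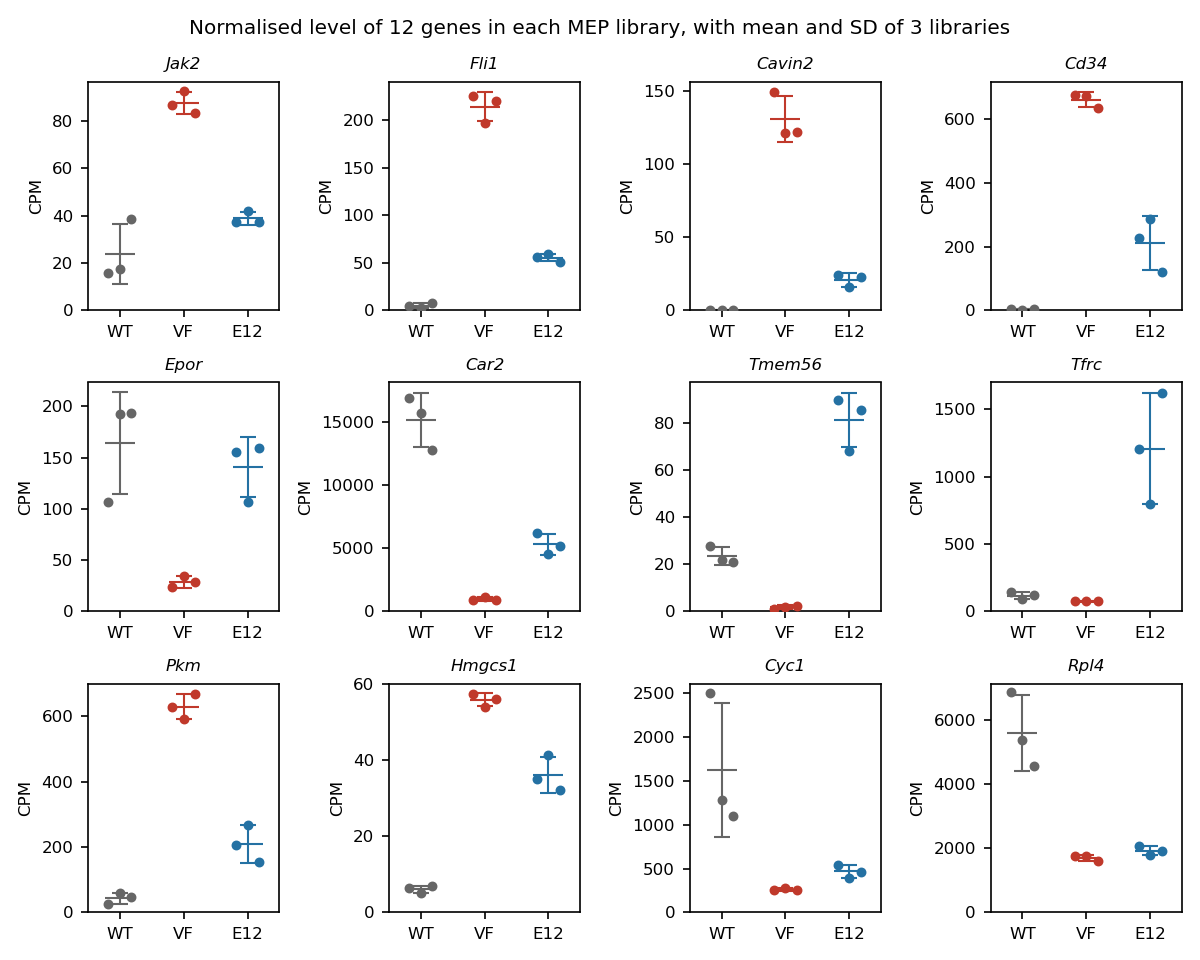
Normalised level in CPM (vertical axes) of 12 genes in each library (points), with the mean and SD of the 3 libraries of each group (bars), grey for WT, red for VF and blue for E12. Fli1, Cavin2 and Cd34 are highest in VF and lowest in WT, Car2 and Epor are lowest in VF, and Tmem56 and Tfrc are highest in E12.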

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

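The tests of the whole cause of the lower complex I transcripts and of RNA of mature red cells were chosen only after the result was seen, as were the length and GC offsets. Changes against WT singled out 19 genes called in opposite directions in VF and E12. All 19 were also called between E12 and VF by edgeR, a difference the selection builds in, so this is no separate test. Of those genes, 6 are named by the rule. Their log2 fold changes in VF and E12 against WT, then E12 against VF, were -3.65, 1.3 and 4.94 for Ank1. They were -1.56, 1.54 and 3.1 for Ccne1, -1.11, 0.93 and 2.04 for Mthfd2 and -1.87, 1.99 and 3.86 for Sptb. For Cad they were -0.7, 0.59 and 1.29, and for Tmem56 -3.71, 1.79 and 5.5. With the offsets the rise of Tmem56 in E12 against WT did not pass (log2 fold change 0.24, adjusted p = 0.62).

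Transcripts of ribosomal proteins and respiratory complexes were lower in both mutant groups than in WT, with a median log2 fold change of the 3 lists below that of all genes by -2.7 in VF and -2.54 in E12. A single unusual WT library is argued against, since without WT 50 the difference was still -1.79 in VF and -1.6 in E12 (SE 0.04 in both). With the offsets the difference shrank to -0.41 (SE 0.09) and -0.19 (SE 0.08). A bias toward short transcripts in WT may thus account for most of the pattern. For complex I -0.78 (SE 0.16) and -0.56 (SE 0.17) remained. The SE is over genes, which are not independent, so this bias stays open as the whole cause. The separate series of WT libraries stays open and cannot be told apart from genotype, because 0 WT libraries share a number series with the mutant ones. An effect of mutant Jak2 on these genes is likewise open.

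Erythroid transcripts were higher and megakaryocyte transcripts lower in E12 than in VF. Without the hemoglobin-rich E12 5 the erythroid median log2 fold change was 3.76 (SE 0.29) and the megakaryocyte one -2.39 (SE 0.24), which argues against that library as the cause. The erythroid genes other than hemoglobins had a median of 3.86 (SE 0.49), or 3.48 (SE 0.36) without E12 5, which argues against RNA of mature red cells. The different weeks after tamoxifen stay open, since 0 weeks hold both E12 and VF libraries, and genotype and time cannot be told apart. As a hypothesis, the alleles may shift progenitors toward different lineages, which a comparison at equal times would test.

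The 6 libraries of a comparison can be split in 10 ways, too few for a share under 0.05. The real split called 6612 genes for VF against WT, 5717 for E12 against WT and 437 for E12 against VF, it was the only 1 of the 10 with as many in each case, and the highest of the others was 0.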

How the results depend on the processing

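For VF against WT the count of called genes stayed within 1.5 times 6612 under all settings, 4749 to 8267 without 1 library and 5084 to 8165 under the other 14. For E12 against WT (5717) it was 3618 to 7307 without 1 library, lowest without E12 2. It was 2934 with only the 2 groups fitted, without VF, the group of least spread. The other settings moved it less than 1.5 times. With the offsets 4133 of the 6612 and 3103 of the 5717 were kept, and on the deposited levels 5096 and 4353. For E12 against VF (437) the count was 19 to 3301 without 1 library, lowest without VF 3. It was 1695 by DESeq2, 924 by limma-voom, 6422 with only the 2 groups fitted, 1784 with limma on the deposited levels, 2559 without WT 50 and E12 5, and 1400 with the length and GC offsets. The count of genes called the same way in both mutants against WT (4791) was 3186 to 6200 without 1 library, lowest without E12 2, and 2475 with only the 2 groups fitted. The correlation of their log2 fold changes was 0.879 to 0.929 without 1 library and 0.83 to 0.916 otherwise. For these shifts the cause was not tested beyond what each setting's construction shows.

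Blocked by replicate number and without WT, E12 against VF gave 5429 genes, 436 of the 437 among them. This rests on numbers 1 and 2, the only ones in both groups, which share only a number. Deviations from group means correlated at 0.01 and 0.103 for these, and at -0.198 to 0.227 for other pairs. Blnk then had a log2 fold change of -0.97 (adjusted p = 0.036), against 0.84 (0.69) with all 9 libraries. The unpaired E12 5 held 66.3 CPM, E12 1 and E12 2 at most 7.89.

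With the length and GC offsets, log2 fold changes turned for Prps2 (-0.26 in VF and -0.26 in E12), Scd2 (-0.32 in VF), Hyou1 (-0.03 in VF), Dnajc3 (-0.95 in VF), Ccng1 (-0.2 in VF) and Srebf1 (-0.08 in E12), all against WT. The median of all genes also fell, but less, from 0.362 to -0.54 in VF and from 0.355 to -0.371 in E12. All but Dnajc3 stayed above it. This shift covers part of the turns. With the offsets 187 and 72 genes were called the other way for VF and E12. The cause was not tested apart from the correction itself. By fry the amino acid response list in VF against WT pointed the other way (adjusted p = 0.026). Of the 43 list calls 43 were lost with an estimated correlation, 6 by fry and 5 with the offsets, and 0 with RLE factors. Fry also gained 17 calls and the offsets 12. What depth limits was not tested, since the counts were not thinned. In simulated counts the fit of all 9 libraries rarely found 2-fold changes. Its real false calls are unknown.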

Other observations

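Counts of rising and falling genes are also given with the offsets and with only the 2 groups fitted. In VF against WT, p53 target genes had 7 of 15 that rose and 2 that fell (8 and 2 over the list alone, median log2 fold change 1.78, camera adjusted p = 0.207, with the offsets 2 and 3 (median 0.67), with 2 groups 4 and 2). Trp53inp1, which promotes cell death, was at 27.9 ± 6.42 against 1.01 ± 0.619 CPM. Ccng1 was at 71.7 ± 6.3 against 30.9 ± 4.5 CPM, and its log2 fold change was -0.20 with the length and GC offsets, under which the median of all genes was -0.54. In the hypoxia response 6 of 19 rose and 2 fell (6 and 2 over the list alone, median log2 fold change 0.85, camera adjusted p = 0.207, with the offsets 5 and 4 (median 0.2), with 2 groups 6 and 0). Of all genes 6612 of 13608 passed in this comparison, so called members alone do not set these lists apart. The prolyl hydroxylase gene Egln3 was at 16.4 ± 1.86 against 0.0708 ± 0.0615 CPM and Ndrg1 at 167 ± 18.2 against 26.5 ± 12.97 CPM. In E12 against WT 8 of 19 rose and 2 fell (8 and 2 over the list alone, median log2 fold change 1.21, camera adjusted p = 0.292, with the offsets 2 and 2 (median 0.06), with 2 groups 3 and 0), and in E12 against VF 1 of 19 rose and 0 fell (1 and 2 over the list alone, median log2 fold change -0.34, camera adjusted p = 0.442, with the offsets 2 and 1 (median -0.17), with 2 groups 3 and 6), P4ha2 being the gene that rose, a call lost without VF 1, VF 2, VF 3, E12 1, E12 2 or E12 5 (adjusted p = 0.07 to 0.2). In the amino acid response of VF against WT 5 of 20 rose and 6 fell (5 and 6 over the list alone, median log2 fold change -0.53, camera adjusted p = 0.448, with the offsets 6 and 13 (median -1.32), with 2 groups 5 and 5), although the mean was 1.26. Vldlr had no count in WT and was at least 1238-fold higher, and the cystine transporter gene Slc7a11 was at 61.02 ± 4.75 against 149 ± 31.7 CPM. In E12 against WT 7 of 20 rose and 1 fell (7 and 1 over the list alone, median log2 fold change 0.34, camera adjusted p = 0.464, with the offsets 6 and 4 (median -0.27), with 2 groups 4 and 0), Sesn2 among those that rose, at 21.6 ± 2.02 against 1.87 ± 0.891 CPM. In E12 against VF 0 of 20 rose and 1 fell (8 and 1 over the list alone, median log2 fold change 0.68, camera adjusted p = 0.00301, adjusted p = 0.21 with an estimated correlation, with the offsets 8 and 1 (median 0.91), with 2 groups 13 and 2). The asparagine synthetase Asns was at 406 ± 46.3 against 78.5 ± 4.69 CPM without passing the test with all 9 libraries (adjusted p = 0.067, and 1.7e-05 with the 2 groups alone). The gene that fell was Vldlr, a call lost without VF 1, VF 2, VF 3, E12 1, E12 2 or E12 5 (adjusted p = 0.081 to 0.23).

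Among endoplasmic reticulum chaperones in VF against WT 4 of 16 rose and 1 fell (1 and 0 over the list alone, median log2 fold change 0.32, camera adjusted p = 0.972, with the offsets 0 and 5 (median -0.22), with 2 groups 1 and 0), and in E12 against WT 1 of 16 rose and 1 fell (1 and 0 over the list alone, median log2 fold change 0.04, camera adjusted p = 0.62 and pointing down unlike the median, with the offsets 1 and 5 (median -0.38), with 2 groups 1 and 0). Of the genes that rose, Hyou1 was at 34.2 ± 7.59 against 12.7 ± 5.96 CPM in VF, with a log2 fold change of -0.03 with the offsets, above the median of all genes. In the interferon response of VF against WT 8 of 38 rose and 6 fell (7 and 5 over the list alone, median log2 fold change 0.57, camera adjusted p = 0.978 and pointing down unlike the median, with the offsets 6 and 7 of 37 (median -0.35), with 2 groups 6 and 4) and in E12 against WT 3 of 38 rose and 9 fell (3 and 5 over the list alone, median log2 fold change 0.31, camera adjusted p = 0.466 and pointing down unlike the median, with the offsets 3 and 8 of 37 (median -0.51), with 2 groups 2 and 3). Ifit2 was at 36.9 ± 4.31 against 3.5 ± 2.21 CPM and the exonuclease Isg20 at 21.2 ± 3.1 against 527 ± 451 CPM in VF. In the pentose phosphate pathway of VF against WT 2 of 10 rose and 3 fell (2 and 3 over the list alone, median log2 fold change -0.42, camera adjusted p = 0.307, with the offsets 0 and 5 (median -0.66), with 2 groups 1 and 1), with Taldo1 at 254 ± 11.1 against 1106 ± 445 CPM. In serine and one-carbon metabolism of VF against WT 0 of 10 rose and 4 fell (0 and 4 over the list alone, median log2 fold change -0.6, camera adjusted p = 0.107, with the offsets 0 and 7 (median -1.07), with 2 groups 0 and 2), and 0.018 without WT 50. Mthfd2 was at 35.9 ± 1.33 against 77.2 ± 16.6 CPM there. In T and NK cell genes of VF against WT 0 of 11 rose and 2 fell (0 and 0 over the list alone, median log2 fold change -0.69, camera adjusted p = 0.369, with the offsets 1 and 1 (median -0.8), with 2 groups 0 and 2), the 2 being Cd2 and Gzma. The call of Cd2 was lost without VF 1, VF 2, VF 3 or WT 50 (adjusted p = 0.095 to 0.14) and that of Gzma without VF 1, VF 2, VF 3, E12 1 or WT 51 (adjusted p = 0.064 to 0.14).

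Between the mutants, 2 more lists moved up in E12 without a called member. In fatty acid synthesis 0 of 15 rose and 0 fell by edgeR, against 4 and 0 at unadjusted p under 0.05, 3 and 0 by DESeq2 and 1 and 0 by limma-voom (2 and 0 over the list alone, median log2 fold change 0.36, camera adjusted p = 0.00996, adjusted p = 0.23 with an estimated correlation, with the offsets 5 and 0 (median 0.6), with 2 groups 9 and 0). Among immediate early genes 0 of 19 rose and 0 fell by edgeR, against 2 and 0 at unadjusted p under 0.05, 0 and 0 by DESeq2 and 0 and 0 by limma-voom (0 and 0 over the list alone, median log2 fold change 0.59, camera adjusted p = 0.0295, adjusted p = 0.36 with an estimated correlation, with the offsets 0 and 0 (median 0.74), with 2 groups 4 and 0), a list call lost without VF 3 (0.12), E12 2 (0.13), WT 50 (0.12) or WT 52 (0.071), with only the 2 groups fitted (0.25), without WT 50 and E12 5 (0.18) and with the offsets (0.13). In the pentose phosphate pathway of E12 against VF 0 of 10 rose and 0 fell by edgeR, against 2 and 0 at unadjusted p under 0.05, 1 and 0 by DESeq2 and 1 and 0 by limma-voom (1 and 0 over the list alone, median log2 fold change 0.32, camera adjusted p = 0.0829, with the offsets 3 and 0 (median 0.46), with 2 groups 7 and 0), and 0.025 without WT 50, 0.033 with the offsets and 0.022 with the 2 groups alone. Of p53 target genes 2 of 15 rose and 0 fell (3 and 0 over the list alone, median log2 fold change 0.61, camera adjusted p = 0.053, with the offsets 5 and 0 (median 0.67), with 2 groups 7 and 1), and the adjusted p was 0.041 without VF 3 and 0.047 without E12 2. The genes were Ccng1 and Zmat3, calls lost without VF 1, VF 2, VF 3, E12 1 or E12 5 (adjusted p = 0.081 to 0.13) and without VF 1, VF 2, VF 3, E12 1, E12 2 or E12 5 (adjusted p = 0.1 to 0.23). Lists of other blood cells depended on E12 5. Among B cell genes of E12 against WT 0 of 12 passed by edgeR, over the list alone or with 2 groups. At unadjusted p under 0.05 1 rose and 4 fell, by DESeq2 or limma-voom 1 and 5. The median log2 fold change was -0.83 (camera adjusted p = 0.0553, and 0.00024 without E12 5). With the offsets 1 rose (median -1.22), and 8 fell without WT 50 and E12 5 (median -3.39). Of E12 against VF, 0 of 12 B cell genes passed by edgeR (also over the list alone), DESeq2, limma-voom or unadjusted p under 0.05. The median log2 fold change was 0.74, but the test pointed down (camera adjusted p = 0.712, and 0.0011 without E12 5). With the offsets (median 0.77) or 2 groups 0 passed. Without WT 50 and E12 5 the median was -1.82 and 2 fell. Of 11 T and NK cell genes in this comparison 0 passed by edgeR, DESeq2, limma-voom or over the list alone. At unadjusted p under 0.05 1 fell. The median log2 fold change was -0.57 (camera adjusted p = 0.0923, 0.00047 without E12 5 and 0.024 with the offsets). With the offsets 0 passed (median -0.53), with 2 groups 2 fell. In monocyte and macrophage genes 0 of 19 rose and 0 fell by edgeR, against 3 and 1 at unadjusted p under 0.05, 1 and 0 by DESeq2 and 0 and 0 by limma-voom (0 and 0 over the list alone, median log2 fold change -0.78, camera adjusted p = 0.207, with the offsets 0 and 0 (median -0.65), with 2 groups 3 and 9), and 0.01 without E12 5. In the interferon response 0 of 38 rose and 0 fell by edgeR, against 2 and 3 at unadjusted p under 0.05, 1 and 2 by DESeq2 and 0 and 1 by limma-voom (0 and 0 over the list alone, median log2 fold change -0.27, camera adjusted p = 0.265, with the offsets 2 and 3 of 37 (median -0.13), with 2 groups 2 and 12), and 0.027 without E12 5.

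In E12 against WT, calls of cell-cycle and nucleotide genes went both ways. With the offsets they were nearly all downward, but the offsets lowered all genes (median from 0.355 to -0.371, and 28.2% of all calls upward). Of S phase genes 4 of 25 rose and 5 fell (3 and 5 over the list alone, median log2 fold change -0.07, camera adjusted p = 0.349, with the offsets 1 and 13 (median -0.78), with 2 groups 1 and 5), and 0.03 without WT 50. Of G2 and M phase genes 5 of 27 rose and 5 fell (5 and 5 over the list alone, median log2 fold change 0.13, camera adjusted p = 0.736 and pointing down unlike the median, with the offsets 0 and 10 (median -0.46), with 2 groups 3 and 4), and in nucleotide synthesis 2 of 19 rose and 7 fell (3 and 7 over the list alone, median log2 fold change 0.1, camera adjusted p = 0.207 and pointing down unlike the median, with the offsets 1 and 8 (median -0.98), with 2 groups 1 and 4), and 0.03 with the offsets. In the pentose phosphate pathway 3 of 10 rose and 1 fell (4 and 2 over the list alone, median log2 fold change 0.31, camera adjusted p = 0.844 and pointing down unlike the median, with the offsets 1 and 3 (median -0.29), with 2 groups 1 and 1), and in serine and one-carbon metabolism 2 of 10 rose and 2 fell (1 and 0 over the list alone, median log2 fold change 0.36, camera adjusted p = 0.832, with the offsets 1 and 1 (median -0.1), with 2 groups 0 and 0).

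Expression from the sex chromosomes differed between libraries of a group. Xist was at 553 CPM in VF 1, 238 in VF 2 and 1.58 in VF 3, while the Y-linked gene Ddx3y was at 35.9, 54.1 and 65.6. In E12 5 Xist was at 1137 and Ddx3y at 0.695 CPM, against 3.32 and 58.6 in E12 1 and 3.01 and 60.0 in E12 2. In WT, Xist was at most 1.9 CPM. VF 1 and VF 2 thus held transcripts of both sexes, and whether each holds cells of more than 1 mouse was not tested, which leaves open what a VF replicate is. E12 5, with Xist and almost no Ddx3y, is also the E12 library with the most hemoglobin and B cell transcripts. Within E12, sex cannot be told apart from the other differences of E12 5.

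Both tests on E12 5 were chosen only after the result was seen. Of 12 B cell genes, 11 were at least 4 times as high in E12 5 as in the higher of E12 1 and E12 2, with Igll1 at 181 CPM against at most 12.8, so B cells in the sort may have contributed, although the sort should remove them. The same held for 7 of 11 T and NK cell genes, 9 of 20 neutrophil and 8 of 19 monocyte genes, 8 of 29 erythroid genes, 6 of them hemoglobin genes, and for 1 of 25 megakaryocyte and 0 of 17 stem cell genes. Erythroid Slc4a1 was at 431 CPM in E12 5 against at most 6.29, Trim10 at 74.1 against 12.9, but Klf1 at 680 against 836. For late erythroid cells in the sort, the median of the erythroid genes other than hemoglobins was higher by 0.31 (SE 0.37), which leaves that explanation open. A biological difference of this library within its group was not tested.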
